A study of Arabidopsis thaliana with 12 samples.

How the data were processed

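Total RNA from whole Col-0 seedlings, labelled with biotin, was hybridised to Affymetrix Gene 1.1 ST array strips, 1 array for each of 12 samples. Per the labels, seedlings were 7 days old. The series text gives 6 or 7 days of growth, without saying which samples had which, 10 seedlings per tube, 24 h of shaking in liquid medium before treatment, 100 ng of RNA per array and 3 repeats on 3 different days. Groups were taken from the sample titles and are mock and IAA at 15 min and at 3 h, with 3 replicates each. The treatment protocol in the labels gives 30 min, 1 h and 3 h and not 15 min, which conflicts with the titles and characteristics. The times used are those of the latter, and what was done at the early time is uncertain to that extent. The authors deposited log2 expression values made with RMA in the oligo package, per the submitters' processing notes, which give no version. RMA subtracts background, equalises the arrays' distributions and summarises the probes of a probe set, so levels near background are compressed and a level can be set only roughly against that of another probe set. The deposited columns do not share one distribution, with interquartile ranges from 2.88 to 3.92. The values were used as deposited, and the genome build and annotation are not given in the sources used here, so no coordinates are printed.

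The value table held 28583 rows. Of these, 16746 were paired with 1 gene by the platform annotation, 758 with several and 11079 with none, and rows with none were left out of the main tests. Names were updated through a RefSeq gene table of assembly TAIR10.1, in which 16601 of the single-gene rows matched by gene number and 96 by locus tag, while 49 kept the platform's symbol. Most loci of the auxin gene lists matched no row by name and are not analysed here. There were 162 loci with over 1 row, none of them among the called genes, and such a locus was represented by its row with the highest mean.

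Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with a constant prior) on the log2 values, with the 4 groups in 1 fit, no block, and no filter on dim probe sets. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 17504 rows with a gene name. The residual degrees of freedom were 8 and the prior ones 3.52. Contrasts were IAA against mock at each time, the difference between these responses, and mock 3 h against mock 15 min. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for annotation and figures. The comparisons, gene lists, rule for named genes and first set of alternatives were fixed before the data were examined.

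The replicate number pairs samples across groups in part, clearly among mock 15 min, IAA 15 min and IAA 3 h and only weakly with mock 3 h. Over the tested rows, deviations from the group mean of same-numbered arrays correlated at 0.781, 0.65 and 0.639 between IAA and mock at 15 min and at 0.127, 0.117 and 0.172 at 3 h, and each of the 12 arrays correlated best with an array of its own number. With a straight line on the mean level taken out of every array, the values at 3 h were 0.0562, 0.0693 and 0.141, of which 2 lie under the threshold of 0.1 used, so the pairing is weaker at 3 h. The mock 3 h array numbered 2 then correlated best with mock 15 min array 1 (0.085) and not with an array of its own number. Array 2 minus array 3, with the line taken out, correlated at 0.242 between IAA and mock at 3 h. Array 1 minus the mean of arrays 2 and 3 correlated there at 0.053. That the numbers stand for the 3 days is drawn from these correlations, since the series text names the days but not their numbers. Between mock at 15 min and at 3 h the correlations were 0.0628, 0.0815 and 0.206. The fit with the replicate number as a block, with 6 residual degrees of freedom, is therefore printed beside a result where it changes the call or moves a count by over 1.5 times. Replicates 2 and 3 of a group correlated at 0.995 to 0.996 and at most 7 of the 28583 values of any replicate pair were identical, so no array was counted as a copy of another.

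The genes named are, for each contrast, the 8 largest rises and the 8 largest falls among called genes whose 3 same-numbered differences share a sign and whose probe set has exactly 1 gene, and for each list and each of the first 3 contrasts up to 4 called members with the largest change, or the member with the smallest p where fewer than 2 were called. A list may be named by fewer members. There were 27 gene lists, of which 19 had a measured member. The 8 tested lists, with at least 3 measured members, were Aux/IAA repressors (8 of 29 measured), GH3 auxin-amino acid synthetases (6 of 8), SAUR small auxin-up RNAs (5 of 80), LBD, PLT and other lateral root founders (4 of 18), auxin biosynthesis (3 of 14), auxin oxidation and glucosylation (4 of 5), expansins (5 of 14) and xyloglucan endotransglucosylases (5 of 14). The 11 smaller lists covered class II homeodomain-leucine zipper factors, auxin transport, ethylene response, cytokinin, touch, clock, hypoxia, heat shock, root hair, root and shoot markers. The 8 lists with 0 measured members, among them auxin response factors, auxin receptors, aquaporins and cell cycle genes, were not tested. Lists were tested with camera at a preset correlation of 0.01, two-sided, adjusted over 32 tests, and again with an estimated correlation and with fry, which asks whether members move one way without comparing them with other genes.

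Values were simulated for all 17504 rows with 100 genes changed at each size. The random noise of a gene had the same spread on every simulated array. The real arrays were unequal, with an SD of the deviation from the group's other arrays of 0.801 on IAA 3 h array 1 and 0.23 on mock 3 h array 2. The rates below therefore describe equal arrays and need not hold for these data. In 1 setting each replicate number added its mean deviation, the same in all 4 groups. This favours the block, and the pairing seen at 3 h was weaker. In this setting the comparison at 15 min recovered 39% of log2 changes of 1 and 97% of changes of 2 without the block, and 84% and 100% with it. The comparison at 3 h recovered 38% and 92% without the block and 81% and 99% with it. False calls numbered 0 without the block, and 14 at 15 min and 11 at 3 h with it. With independent noise instead, 62% of changes of 1 were recovered at 15 min without the block and 60% with it. At 3 h these were 51% and 41%. False calls without and with the block were then 10 and 12 at 15 min, and 8 and 12 at 3 h. Alternatives tried were the fixed and the random replicate block, leaving out the dimmest 25% of rows, all rows, median centring, a further quantile normalization, an intensity trend with robust variances, array weights, a 2-fold minimum, the 6 compared arrays alone, and each array left out in turn. Leaving out the arrays numbered 1, and pairs of these choices, were added after seeing the data.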

Results

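Whole Arabidopsis thaliana seedlings of the Col-0 accession were shaken in liquid medium and given either 0.1% DMSO (mock) or 1 µM indole-3-acetic acid (IAA), the main natural auxin, for 15 min or 3 h. Each of the 4 groups held 3 arrays, numbered 1 to 3, from an experiment that was repeated on 3 different days. Every array gave a log2 level for 28583 probe sets, of which 17504 could be paired with a gene name and were tested. Array medians lay between 4.72 and 4.79. The interquartile range was 3.89 to 3.92 on the 8 arrays numbered 2 and 3, and 3.79, 3.53, 3.46 and 2.88 on the arrays numbered 1 of mock 3 h, mock 15 min, IAA 15 min and IAA 3 h. The IAA 3 h array numbered 1 had a median correlation of 0.94 with the other arrays, against 0.99 for the arrays numbered 2 and 3. The number of arrays limits the precision. The p-values without the block measure the spread between arrays within groups, pooled over the 4 groups. Those with the block measure the spread left after the replicate number is taken out, also pooled over the 4 groups. Both rest on 3 repeats of 1 experiment.

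**Figure D1:**
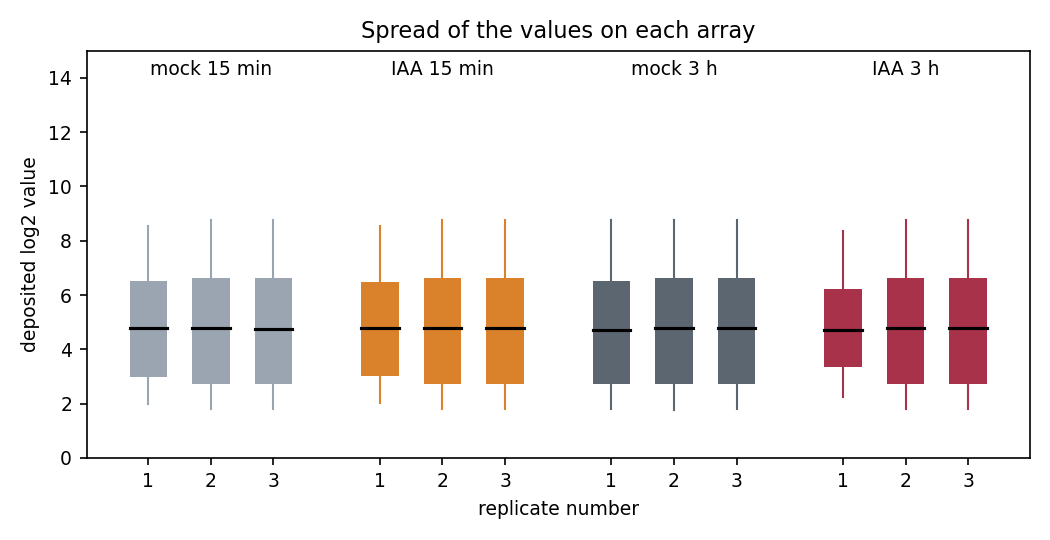
Deposited log2 values on each of the 12 arrays by group and replicate number. The box spans the 25th to the 75th percentile, the black bar is the median and the line runs from the 5th to the 95th percentile. The box of the IAA 3 h array numbered 1 spans 2.88 log2 units, against 3.79 for the mock 3 h array of the same number.

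The first comparison asks which transcripts had moved after 15 min of IAA. With the replicate number taken into account as a block, 4 genes were higher and 0 lower, namely GH3.1, HAT2, LBD29 and AT1G68360. GH3.1, which encodes an enzyme that joins auxin to amino acids, was 3.19-fold higher (log2 change 1.67, SE 0.21, n = 3 against 3; limma adjusted p 0.0841 without the block and 0.0024 with it, and 5.13e-06 to 0.735 over all 20 alternatives). HAT2, a class II homeodomain-leucine zipper gene, was 3.98-fold higher (log2 change 1.99, SE 0.31; adjusted p 0.127 without the block and 0.0232 with it, range 5.13e-06 to 0.948). LBD29, a transcription factor gene of lateral root initiation, had a log2 change of 2.69 (SE 0.53; adjusted p 0.567 and 0.0232, range 0.000241 to 1), and AT1G68360 one of 0.90 (SE 0.14; adjusted p 0.119 and 0.0407, range 0.000105 to 1). All 4 were higher in 3 of 3 same-numbered pairs. GH3.1 and HAT2 were named by the rule for lists, while LBD29 and AT1G68360 were singled out after their values were seen. The fit without the block called 0 genes at an adjusted p under 0.05. An unadjusted limma p under 0.05 was reached by 111 genes without the block and 214 with it. Both counts lie below a share of 0.05 of the 17504 genes tested, which would be reached with no change at all. They are therefore no sign of further changed genes. Leaving out the 4 arrays numbered 1 gave 11 genes without the block, all higher, and leaving out the IAA 15 min array numbered 1 alone gave 1.

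Among gene lists fixed before the data were examined, 3 stood above the other genes at 15 min. The GH3 list had a mean log2 change of 0.68 over 6 measured members, 5 of them positive (camera adjusted p 1.04e-09, adjusted p 0.0295 with an estimated correlation). Besides GH3.1, its members GH3.3 (log2 change 1.63, SE 0.38) and WES1, also known as GH3.5 (0.70, SE 0.27), passed when adjusted over the list alone, so that 3 of the 6 did, against 0 over all genes tested. The list of LBD, PLT and other lateral root founders had a mean of 1.08 over 4 members (adjusted p 1.14e-07, adjusted p 0.0113 with an estimated correlation), and 2 of the 4, LBD29 and LBD16 (log2 change 1.70, SE 0.30), passed when adjusted over the list alone. The Aux/IAA list, the repressors of auxin-response transcription, had a smaller mean of 0.18 and a median of 0.08 over 8 members, 5 of them positive (adjusted p 0.00126, adjusted p 0.0295 with an estimated correlation), and 1 member, IAA29 (log2 change 1.00, SE 0.25), passed when adjusted over the list alone. With the replicate block and an estimated correlation the adjusted p was 0.0749 for Aux/IAA, 0.0356 for GH3 and 0.0356 for the lateral root founders, and over 12 alternatives it ran from 0.00229 to 0.0749, from 6.85e-13 to 0.0625 and from 9.22e-10 to 0.0356.

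The other lists with 3 or more measured members did not pass at 15 min. The SAUR list of small auxin-up RNAs had a mean log2 change of 0.23 but a median of -0.05 over 5 members (adjusted p 0.241). Its member AT2G18010 (SAUR10) had a log2 change of 1.31 (SE 0.27; adjusted p 0.831) and was the 1 member that passed when adjusted over the list alone. Mean log2 changes were -0.05 for auxin biosynthesis (adjusted p 0.604), -0.10 for auxin oxidation and glucosylation (adjusted p 0.42), 0.13 for expansins (adjusted p 0.204) and 0.04 for xyloglucan endotransglucosylases (adjusted p 0.734, median -0.01), with 0 members passing when adjusted over the list alone in any of these. The 11 lists with fewer than 3 measured members held 14 genes. HAT2 was the only one of them called with the block, and the other 13 had log2 changes between -0.24 and 0.48. The root-enriched transcript PYK10 changed by 0.08 (SE 0.15) and the leaf transcript RCA, rubisco activase, by 0.03 (SE 0.12), with adjusted p 1 for both.

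**Figure D2:**
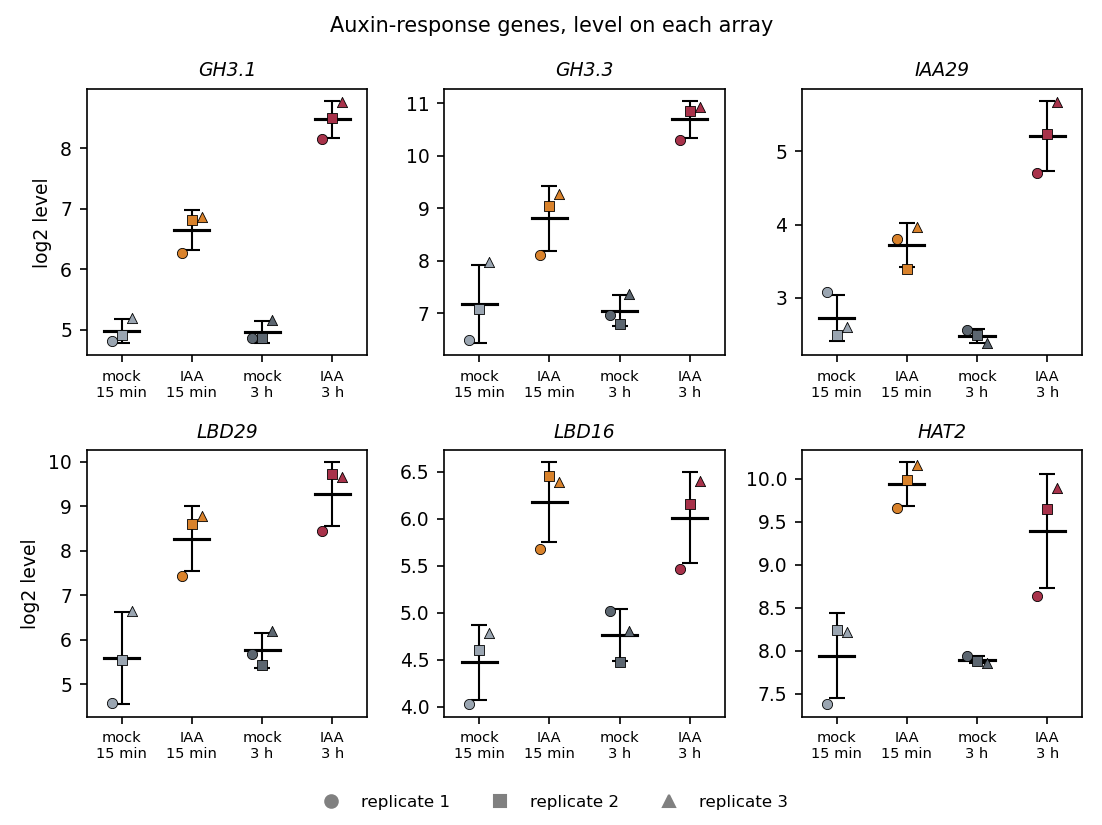
Log2 level of 6 auxin-response genes on each array, by treatment and time. Points are arrays, shaped by replicate number, and the bars are the group mean ± SD (n = 3). The mean of GH3.1 was 4.98 in mock and 6.65 in IAA at 15 min, and 4.97 and 8.48 at 3 h.

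After 3 h of IAA, 30 genes were higher and 12 lower than in mock at the same time. Among rows with a gene name, the largest rises belonged to auxin-response genes. GH3.3 was 12.4-fold higher (log2 change 3.64, SE 0.38, adjusted p 0.00227), GH3.1 11.4-fold (3.51, SE 0.21, adjusted p 3.23e-05), LBD29 11.4-fold (3.52, SE 0.53, adjusted p 0.0223), IAA29 6.62-fold (2.73, SE 0.25, adjusted p 0.00081) and WES1 4.12-fold (2.04, SE 0.27, adjusted p 0.0109). The mock 3 h level of IAA29, 2.48, lay below the 25th percentile of each of those arrays (2.72 to 2.73), where values are compressed, so its fold is less exact. Next came AT1G30760, a berberine bridge enzyme-like oxidoreductase gene (3.95-fold), AT3G60650 (3.83-fold) and AT5G65320, a basic helix-loop-helix factor gene (3.53-fold), with adjusted p from 0.00961 to 0.0155. Each of these rises was seen in 3 of 3 same-numbered pairs, which the rule for naming them required. With the replicate block 45 genes were higher and 45 lower, including all 42 of the genes called without it. The block fit pools its spread over all 4 groups, and the pairing was weaker at 3 h. Its errors can therefore understate the spread between the 3 h pairs, and the calls it adds are less certain.

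Among genes called without the block, falls at 3 h were led by AT3G01190, a class III peroxidase gene, which was 6.84-fold lower (log2 change -2.77, SE 0.24, adjusted p 0.000592), and by AT3G01260, which was 3.89-fold lower with the smallest error among them (-1.96, SE 0.13, adjusted p 5.19e-05). AT1G05660 (-1.83), AT3G50130 (-1.80), AT5G02350 (-1.64), AT2G47540 (-1.57), AT3G27950 (-1.56) and EXPB1, a beta-expansin gene (-1.49), followed, with SEs from 0.21 to 0.28 and adjusted p from 0.00961 to 0.0459. Each fell in 3 of 3 same-numbered pairs, which the rule for naming them required. The mean level of AT3G01190 was 7.92 ± 0.38 (SD, n = 3) in mock and 5.15 ± 0.20 in IAA at 3 h, and that of EXPB1 was 6.08 ± 0.12 and 4.59 ± 0.52.

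**Figure D3:**
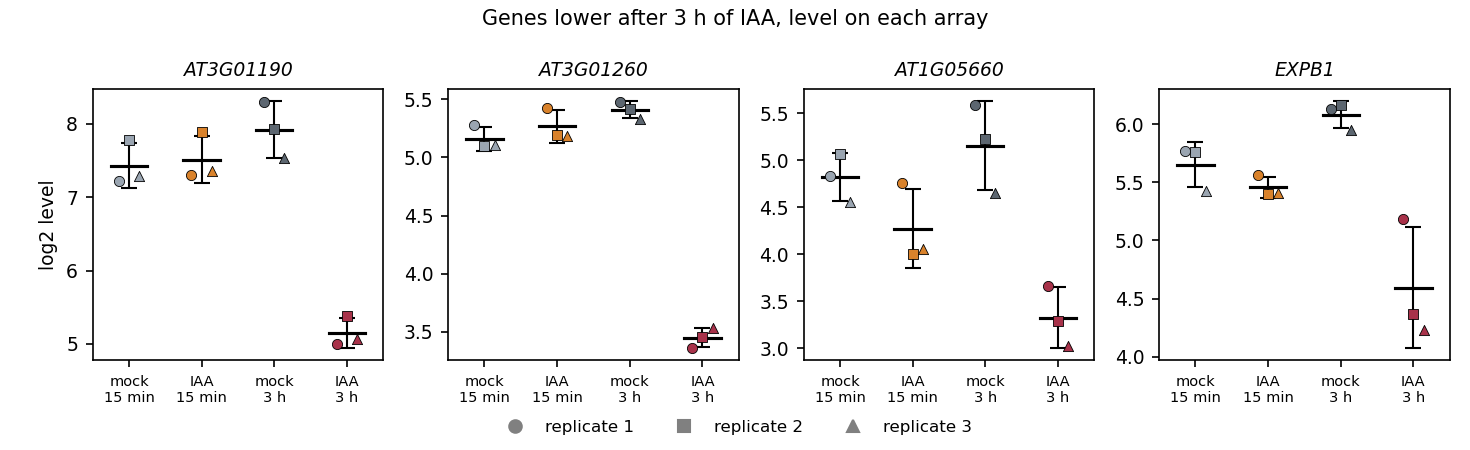
Log2 level of 4 genes that were lower after 3 h of IAA, on each array by treatment and time. Points are arrays, shaped by replicate number, and the bars are the group mean ± SD (n = 3). The mean of AT3G01260 was 5.16 in mock and 5.27 in IAA at 15 min, and 5.41 and 3.45 at 3 h.

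The same 3 lists passed at 3 h. In the GH3 list (mean log2 change 1.61, camera adjusted p 3.57e-08, adjusted p 0.0295 with an estimated correlation) 3 of 6 members were called higher, namely GH3.3, GH3.1 and WES1, and 3 did not pass. Among the lateral root founders (mean 1.44, adjusted p 1.25e-06, adjusted p 0.0113 with an estimated correlation) 2 of 4 were called higher, LBD29 and PUCHI, an AP2/ERF factor gene of lateral root primordia (log2 change 0.86, SE 0.14, adjusted p 0.0305), and LBD16 (1.24, SE 0.30, adjusted p 0.202) joined them when adjusted over the list alone. In the Aux/IAA list (mean 0.52, median 0.25, adjusted p 0.000826, adjusted p 0.0295 with an estimated correlation) IAA29 was the 1 member of 8 called higher, over all genes and when adjusted over the list alone. The 8 were dim, with a median level of 2.46, and 7 had positive changes. Without the arrays numbered 1 the list mean was 0.495. With the replicate block and an estimated correlation the adjusted p was 0.0749 for Aux/IAA, 0.0532 for GH3 and 0.0356 for the lateral root founders, and over 12 alternatives it ran from 0.000495 to 0.0749, from 2.33e-15 to 0.0532 and from 2.34e-09 to 0.0356.

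Single members of other lists came close to the threshold or passed it with the replicate block. At 3 h HAT2 stood at 2.82 times its mock level (SE 0.31 on the log2 scale; adjusted p 0.123 without and 0.0169 with the block, range over the alternatives 1.26e-06 to 0.45). The same-numbered log2 differences of HAT2 at 3 h were 0.699, 1.76 and 2.03, beside an SE of 0.22 with the block. AT2G18010 had a log2 change of 1.23 (SE 0.27; 0.161 and 0.0462, range 0.00596 to 0.635), and YUC6, a flavin monooxygenase gene of auxin synthesis, one of -0.97 (SE 0.18; 0.0557 and 0.0117, range 0.000433 to 0.361). The lists themselves did not pass. Mean log2 changes were 0.33 for SAUR (adjusted p 0.33), -0.18 for auxin biosynthesis (adjusted p 0.42, median 0.20, so that mean and median differ in sign), -0.06 for auxin oxidation and glucosylation (adjusted p 0.734), 0.20 for expansins (adjusted p 0.696) and 0.10 for xyloglucan endotransglucosylases (adjusted p 0.734). When adjusted over the list alone, AT2G18010, YUC6, AT1G14120 of the oxidation list (-0.55, SE 0.18, not with the replicate block) and EXPA8 (0.93, SE 0.27) passed, 1 in each of 4 lists, and 0 xyloglucan endotransglucosylase genes. Of the 14 genes in the 11 smaller lists, those other than HAT2 had log2 changes between -1.09 and 0.67, with no adjusted p under 0.78. PYK10 changed by -0.19 (SE 0.15) and RCA by -0.01 (SE 0.12).

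**Figure D4:**
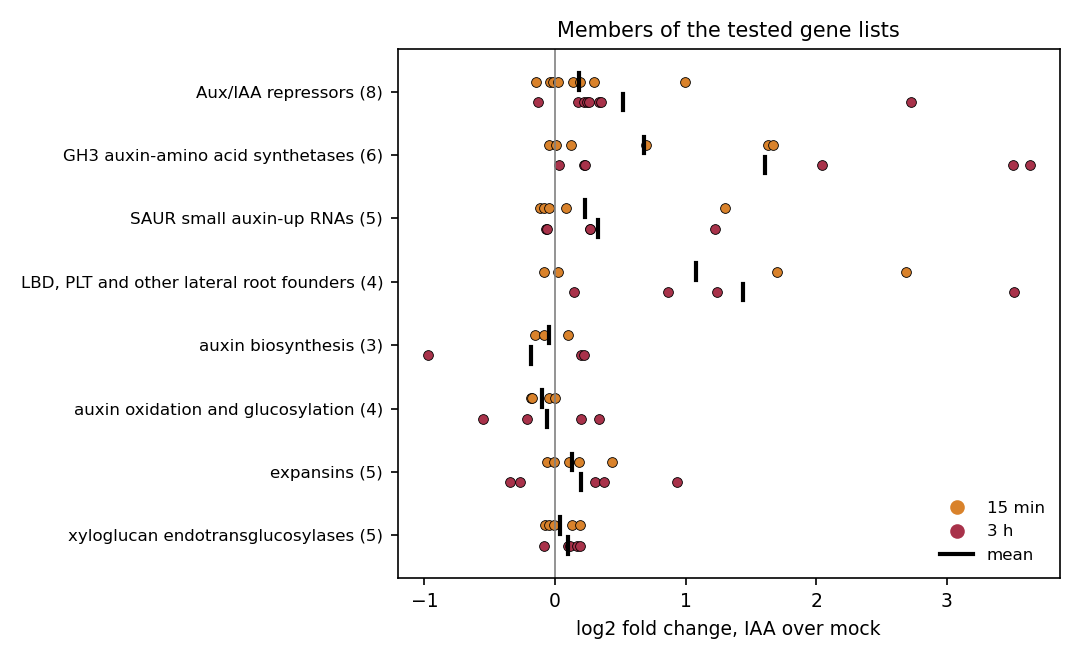
Log2 fold change of IAA over mock for each measured member of the 8 tested gene lists, at 15 min and at 3 h. Points are genes, black bars are list means, and the number of measured members is in brackets. The GH3 mean was 0.68 at 15 min and 1.61 at 3 h, carried by 3 of its 6 members.

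The count at 3 h moved with the arrays used. Leaving out 1 array at a time gave 61 genes without the IAA 3 h array numbered 1, 9 without mock array 1, 9 without mock array 2, 16 without mock array 3, 8 without IAA array 2 and 9 without IAA array 3, while leaving out all 4 arrays numbered 1 gave 163 genes, which held 41 of the 42.

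The difference between the responses, the change at 3 h minus that at 15 min, was tested directly. AT3G01190 (difference -2.86, SE 0.34, adjusted p 0.0236) and AT3G01260 (-2.07, SE 0.18, adjusted p 0.00251) passed, having changed by 0.09 (SE 0.24) and 0.11 (SE 0.13) at 15 min. Both differences were negative in 3 of 3 same-numbered sets of arrays, which the rule for naming them required. GH3.1, named by the rule for lists, had a difference of 1.84 (SE 0.30, adjusted p 0.233 without the block and 0.00862 with it, range over 25 alternatives 0.000165 to 0.728), and was the third gene called with the replicate block. IAA29 had a difference of 1.73 (SE 0.35, adjusted p 0.5). Among the lists, GH3 had a mean difference of 0.93 (adjusted p 6.12e-06), which was lost with an estimated correlation (adjusted p 0.0687, range over 18 alternatives 8.1e-10 to 0.0716). The Aux/IAA list (mean difference 0.34, adjusted p 0.0603), the lateral root founders (0.36, adjusted p 0.106), SAUR (0.10, adjusted p 0.747), auxin biosynthesis (-0.14, adjusted p 0.517), auxin oxidation and glucosylation (0.04, adjusted p 0.988), expansins (0.07, adjusted p 0.96) and xyloglucan endotransglucosylases (0.06, adjusted p 0.812) did not pass. The biosynthesis median was 0.13, opposite in sign to its mean, and the oxidation and expansin lists tested downwards in spite of their positive means. When adjusted over the list alone, 3 GH3 members, 1 Aux/IAA member and 1 lateral root founder passed upwards and 1 biosynthesis member downwards. Leaving out single arrays gave 1 to 8 genes, 8 without the IAA 3 h array numbered 1. AT3G01190 lost its call without any one of mock 3 h array 1 or 2, IAA 3 h array 3, mock 15 min array 1 or 3, or IAA 15 min array 1, 2 or 3, and AT3G01260 kept its call in each case.

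Genes called at both times were counted with the replicate block, since the fit without it called 0 at 15 min. GH3.1, HAT2 and LBD29, 3 of the 4 genes higher at 15 min, were also among the 45 higher at 3 h, against 0.0103 for independent lists (Fisher's exact test, two-sided, p 6.34e-08). Both lists came from 1 fit with the same spread for each gene, and genes are not independent units, so this p-value is only descriptive. AT1G68360, the remaining gene, changed by -0.06 (SE 0.14) at 3 h, and its difference between times was -0.96 (SE 0.19, adjusted p 0.5). Across the 17504 probe sets, which are not independent replicates, the fold changes at the 2 times had a Pearson correlation of 0.189 and a Spearman correlation of 0.127, from comparisons that share no arrays.

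Mock seedlings at 3 h were set against mock seedlings at 15 min as the background of time in the tube. By limma 0 genes passed, with or without the replicate block. An unadjusted p under 0.05 was reached by 499 genes without the block and 957 with it. A share of 0.05 of the 17504 genes, expected with no change at all, is more than the 499 and close to the 957. None of the 8 tested lists passed, with mean log2 changes from -0.15 for xyloglucan endotransglucosylases (adjusted p 0.42) to 0.10 for the lateral root founders (adjusted p 0.604), and the Aux/IAA and GH3 lists at 0.03 each. The medians of the GH3 (-0.06), auxin biosynthesis (-0.07) and expansin (-0.07) lists had the opposite sign to their means. No member of the 8 lists passed when adjusted over the list alone. Without the 4 arrays numbered 1, 30 genes were higher and 88 lower at 3 h.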

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

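The counts over other splits, the look at unnamed probe sets and the tests of root share and of the peroxidase family were chosen after the results were seen, although the outcome for the family without the genes first noticed was not known when it was set up. AT3G01190 and AT3G01260 were picked out because the IAA effect differed between the times: the change at 3 h minus that at 15 min was -2.86 and -2.07 on the log2 scale. The GH3 list was picked out in the same way, with a mean difference of 0.932, a call lost with an estimated correlation (adjusted p 0.0687). Of 100 splits of the arrays drawn within each time, the real one included, 9 called at least the 2 genes of the real split, and the highest of the other splits called 7, so chance is not excluded for that count. Among those of the drawn splits that parted all same-numbered pairs as the real one does, the highest other called 2. All 9 kept mock and IAA apart at 3 h, so the count rests on the change at 3 h more than on the contrast with 15 min.

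Rows without a gene name also carried signal. In a fit to all 28583 rows, 9 of the 11079 unnamed rows were called at 15 min, all higher, 46 at 3 h, 29 higher and 17 lower, and 3 for the difference between times. The largest rise among the unnamed rows called at 3 h was 3.94, and 0.415% of unnamed rows were called at 3 h, against 0.269% of named ones. With the replicate block 91 unnamed rows were called at 3 h, 48 higher and 43 lower, or 0.821% against 0.583% of named ones.

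AT3G01190 belongs to the class III peroxidases, and a second member, AT4G30170, was also called lower at 3 h (log2 change -1.07, SE 0.18, adjusted p 0.0425). From a list of 73 loci written before the test, 64 were measured, and their mean change at 3 h was -0.19, with 39 of 64 lower, 2 called lower and 1, AT5G14130, called higher (1.33, adjusted p 0.0484). A smaller share of root tissue in the IAA samples would lower abundant root transcripts alike, but PYK10 changed by -0.193 (SE 0.153) at a level of 11.3, on arrays reaching 12.7, where 0.5 of the mean fall of the 2 genes would be -0.96, which argues against this as the whole cause of their falls. Without the 2 genes, the remaining 62 still lay below other genes (mean -0.13, camera adjusted p 0.00163 over the 2 IAA comparisons, adjusted p 0.0154 with an estimated correlation, 0.0336 with the replicate block as well), in 3 of 3 same-numbered pairs. For this smaller shift a lower root share stays open beside a response of the family to auxin, since PYK10 minus the mean of the 62 was -0.0631 (SE 0.155), the root hair genes EXPA18 and EXPA7 had a mean of -0.199 (-0.34 and -0.06) and the shoot gene RCA changed by -0.01, none of them called. The PYK10 change lay mostly in pair 1, with same-numbered differences of -0.562, -0.0398 and 0.0228. Those of the 62 were -0.131, -0.162 and -0.0971, so PYK10 stood below them in pair 1 and above them in pairs 2 and 3.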

How the results depend on the processing

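The counts over other splits, leaving out all arrays numbered 1 and the combined settings were added after seeing the data. In the order of 15 min, 3 h, difference, mock against mock and overlap, the counts without a block were 0, 42, 2, 0 and 0. With the replicate block, 4 and 90 genes were called at the 2 times and 3 were shared, and the difference (3) and mock against mock (0) stayed within 1.5 times. A random replicate block gave 8, 109, 5 and an overlap of 6. All rows gave 12, 93, 5 and 7 from a wider set of rows. A further quantile normalization gave 3 at 15 min, 4 for the difference and 3 shared. Array weights gave 42, 546, 127, 458 and 25, with the lowest weight, 0.0667, on the IAA 3 h array numbered 1. The 6 compared arrays alone gave 6 at 3 h, from fewer samples. The replicate block without arrays numbered 1 gave 15, 298, 62, 158 and 12. The replicate block with all rows gave 22, 193, 6 and 13. The replicate block without the IAA 3 h array numbered 1 gave 7, 102, 14 and 5. Otherwise the cause was not tested. Leaving out arrays gave 0 to 11 genes at 15 min, 8 to 163 at 3 h, 1 to 21 for the difference, 0 to 118 for mock against mock and 0 to 8 shared, with the highest value of each without all arrays numbered 1. Leaving out the dimmest rows, median centring, the trend with robust variances and the 2-fold minimum kept every count within 1.5 times.

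Of the 19 gene results called without a block, 6 passed in every alternative, namely GH3.3, GH3.1, IAA29, AT3G01190 and AT3G01260 at 3 h and AT3G01260 for the difference, and 15 of the 21 not called passed in some. At 3 h LBD29, WES1, AT1G30760, AT5G65320, EXPB1 and PUCHI lost their calls without any one of mock arrays 1, 2 and 3 and IAA arrays 2 and 3, and AT3G27950 without any of the 6. AT1G05660 and AT2G47540 lost theirs without mock 1, mock 2, IAA 2 or IAA 3, AT3G50130 and AT5G02350 without mock 1, mock 2 or IAA 2, and AT3G60650 without mock 1, IAA 2 or IAA 3. Other settings also ended calls at 3 h: EXPB1 and PUCHI after the further quantile normalization, PUCHI at the 2-fold minimum, AT3G27950 after median centring and with the replicate block without the IAA 3 h array numbered 1, and with the 6 compared arrays alone these 3 and LBD29, WES1, AT3G60650, AT5G65320, AT1G05660, AT3G50130, AT5G02350 and AT2G47540. All called genes kept their direction. Those that turned sign were uncalled and near 0. RCA at 3 h was 0.0294 after the further quantile normalization and -0.0547 to 0.0282 without single arrays or all numbered 1. At 15 min RCA was -0.0420 with array weights, -0.0194 with the replicate block and no arrays numbered 1, and -0.0194 to 0.0758 without arrays, and PYK10 was -0.00831 to 0.126. Of 272 list means with arrays left out, 29 turned sign, and of 160 under other settings 2 did, all in lists that had not passed. The latter, without the dimmest rows, were auxin oxidation and glucosylation for the difference (-0.0714) and Aux/IAA for mock against mock (-0.00814). With arrays left out, the mean of xyloglucan endotransglucosylases was -0.0244 to 0.0789 at 15 min and -0.00791 to 0.209 at 3 h, and that of auxin biosynthesis -0.114 to 0.00451 at 15 min. For the difference, means ran from -0.199 to 0.277 for SAUR, -0.0301 to 0.122 for oxidation, -0.109 to 0.194 for expansins and -0.0451 to 0.172 for xyloglucan endotransglucosylases. For mock against mock they ran from -0.0112 to 0.0549 for Aux/IAA, -0.120 to 0.178 for GH3, -0.309 to 0.0471 for SAUR, -0.0576 to 0.259 for the lateral root founders, -0.0472 to 0.0806 for auxin biosynthesis, -0.0304 to 0.0363 for oxidation and -0.0858 to 0.218 for expansins. Lists past the threshold numbered 0 to 3 for the difference, where Aux/IAA joined GH3 without the dimmest rows, mock 15 min array 1, IAA 15 min array 2 or 3, or mock 3 h array 3, and the lateral root founders without mock 15 min array 1, IAA 15 min array 2 or 3, IAA 3 h array 1 or all arrays numbered 1. For mock against mock, xyloglucan endotransglucosylases passed without mock 3 h array 1 or all arrays numbered 1, and expansins without mock 15 min array 1. At 15 min SAUR passed without the dimmest rows, mock array 1 or all arrays numbered 1, and expansins without mock array 1 or IAA array 2. By fry the Aux/IAA and GH3 lists missed the threshold at 15 min (adjusted p 0.0625 for each), while the lateral root founders passed at both times in all 12 alternatives. Among the named genes and tested lists, the replicate block changed no call other than those given with the results. Most of the genes that it added at 3 h are not named here. Neither median centring nor the further quantile normalization moved the median of all genes by over 0.1. Signal over background limits dim genes such as PUCHI, whose mean level was 2.29, and IAA29 and AT2G18010, at 2.48 and 2.38 in mock at 3 h.

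With 10 splits of 6 arrays, no share under 0.05 can be reached. The real split at 3 h called 42 genes and the highest other 0, so that 1 of 10 splits called as many. With the replicate block the real split called 90 at 3 h and 4 at 15 min, and the highest other 0, again 1 of 10 in each. At 15 min without the block and for mock against mock, the real split and the highest other called 0, so that 10 of 10 called as many. Among the 4 splits that part all 3 same-numbered pairs, the highest other was 0 as well.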

Other observations

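The tests and genes in this part were chosen after the data were seen, and only the test of a shared day beyond the scale was set up before its outcome was known, though the correlations of same-numbered arrays as deposited had been seen. Beyond the lists, CLE44, which encodes a peptide signal of the vascular stem cell niche, was higher at 3 h (log2 change 1.66, SE 0.22, adjusted p 0.0115), as was AT2G34655, a small gene (1.05, SE 0.17, adjusted p 0.0374). The AP2/ERF factor gene listed as tny fell by 1.42 (SE 0.18, adjusted p 0.00961). Among 28 gene families defined by their shared symbol, each with at least 8 measured members, 7 of 56 tests over the IAA comparisons passed. Among them were Aux/IAA at both times, repeating the 8 genes of the fixed list, and, at 15 min, the BZIP family (mean 0.11 over 17 members, adjusted p 0.0294, 0.214 with an estimated correlation). For Aux/IAA the camera adjusted p over these 56 tests was 0.155 at each time with an estimated correlation. None of the 7 passed with an estimated correlation. The TBL family, related to cell wall acetylation, had a mean log2 change of -0.11 at 3 h over 23 members, 8 of them positive (camera adjusted p 0.0294, 0.548 with an estimated correlation, 0.0352 without the arrays numbered 1).

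Families of dim genes stood higher at 3 h. The 64 LCR genes of the defensin-like kind, median level 2.02, had a mean log2 change of 0.26 and the 12 SCRL genes one of 0.27 (adjusted p 0.000206 and 0.0472, and 0.912 with an estimated correlation for each). Without the arrays numbered 1 the means were 0.04 and 0.10, with adjusted p 0.54 and 0.602.

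The arrays numbered 1 stood apart from the other arrays, most of all the IAA 3 h array. A narrower signal scale on these arrays would raise dim rows and lower bright ones, as a straight line on the mean level. Over the 4 arrays this line accounted for a squared correlation of 0.17, from 0.0211 on mock 3 h to 0.349 on IAA 3 h, too much to set the scale aside. Noise lowers this value and a straight line misses a curved one, so it cannot tell whether the scale is the whole cause. After the line was taken out of every array, same-numbered arrays of different groups correlated with a median of 0.316 (range 0.00905 to 0.74 over 18 pairs), against a median of -0.065 and a highest value of 0.495 for other numbers, the latter between arrays 2 and 3, which deviate together from array 1. Array 1 minus the mean of arrays 2 and 3 correlated at 0.583 to 0.74 among mock 15 min, IAA 15 min and IAA 3 h but at 0.011 to 0.053 with mock 3 h, so a day shared by all 4 arrays stays open, while array 2 minus array 3 correlated at 0.115 to 0.293 in all 6 pairs of groups.

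The 12 genes lower at 3 h had moved little at 15 min, with a mean log2 change of -0.14 (median -0.08) against -1.64 at 3 h, and 8 of the 12 in the same direction. The 30 genes higher at 3 h had a mean of 0.46 but a median of 0.16 (SD 0.65), with 7 of the 30 not in the same direction. Levels near the floor were argued against, since the median level of the 12 genes in mock at 15 min was 5.67, with 0 of 12 among the dimmest 25% of rows by their mean over all arrays, and 11 of the 12 stood in mock at 15 min above their own level in IAA at 3 h by over 2 SE, which their choice by the fall at 3 h favours. The ratio of each number's mean early change to the mean late change over all arrays was lower for the falling genes in 3 of 3 replicate numbers. The difference was -0.203 (SE 0.0172 over the numbers), an SE that leaves out the spread of the late change. This comparison restates the pattern on genes chosen by their change at 3 h. By medians the ratio was 0.0526 for the falling and 0.119 for the rising genes, and 0.102 and 0.0739 for the 45 and 45 genes called with the replicate block. Noise that hides falls at 15 min and falls that come later than rises therefore cannot be told apart here.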
